A study of Homo sapiens with 2 samples.

How the data were processed

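ATAC-seq was performed on wild-type, untreated MCF-7 cells in 2 libraries, which form 1 group with replicate numbers taken from the sample titles. The deposited data are 1 peak list per library. Per the submitters' processing notes, reads were handled with Bowtie2 and MACS2 on GRCh38 (hg38). Tool versions, the handling of duplicates and of mitochondrial or multiply mapped reads, any shift for the Tn5 cut and any exclusion of problem regions are not given in the sources used here. Any of these could change which peaks are called. The peak names carry the replicate, so peaks were called per library and not on pooled reads. Per the file headers, each row gives an interval, a fold change over the caller's local background (a ratio), a −log10 p-value, a −log10 q-value, a score of 10 times the −log10 q-value and a summit position; these are the deposited values of the authors' peak caller. The smallest −log10 q was 1.31 in replicate 1 and 1.30 in replicate 2, and the narrowest interval was 200 bp in both. Folds and p-values describe a peak within its own list and were used only to rank, filter or describe peaks there. They were not compared as levels between libraries.

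Rows that share an interval and differ in summit were joined into 1 region with the highest fold of its rows; 16829 regions of replicate 1 and 16574 of replicate 2 had more than 1 summit. Chromosomes 1 to 22 and X were analysed. Depth per sample is unknown, since the lists hold no counts, so no limit of detection per region can be given, and the absence of a peak says only that none was called. Intervals of shares are 95% Wilson intervals and cover counting error only. The lists were not copies of one another: 2.07% of the shared regions outside the class of 219 to 225 bp had the same boundaries in both. With 2 libraries that may be technical repeats, the spread between them does not measure variation between cultures. No test between conditions was possible with 1 group.

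Overlap was counted from 1 bp. Chance overlap came from 10 seeded placements of all regions at random on their own chromosomes, whose length was taken as the highest coordinate in the gene table or the lists; assembly gaps were not excluded. Gene positions came from a RefSeq gene table of GRCh38.p14, the same build, with 19970 protein-coding genes on the chromosomes used; every symbol in the fixed lists matched it. The table has neither strand nor transcripts and no genome sequence was used. The plan had named canonical transcript starts; windows of 1000 bp either side of both annotated gene ends were used in their place, which adds 3' ends to every count, and a gene with internal promoters can be missed. The planned search for transcription factor motifs at summits, the matching on CpG content, the use of all transcript starts and the removal of repeats or mitochondrial copies need a sequence or transcripts and were not run.

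A gene was called accessible when a peak of each replicate overlapped its windows. A gene was said to have no peak when none lay in these windows, and it can still hold regions in its body. Lists were compared with all other protein-coding genes by Fisher's exact test (two-sided) with Benjamini-Hochberg adjustment over 18 lists, 16 written out by symbol and 2 (olfactory receptor and ribosomal protein genes) by symbol pattern. The neighbourhood count of a gene is the mean number of shared regions within 50 kb of its 2 ends. A list's median was set against 10000 random lists matched on the tenth of gene starts within 50 kb (two-sided permutation p, adjusted over the lists; the smallest p these can give is 2e-04). Since neighbouring genes share regions, each list was also moved as 1 block along the gene order 10000 times. The rule for named genes was fixed before the data were examined: ZNF408, SETD1A, ESR1, GATA3, FOXA1, TFF1, GREB1, PGR, CD274, B2M, HLA-A and CDKN2A; from each list up to 3 accessible members with the highest lower-of-2 rank of fold and up to 3 members without a peak, in alphabetical order; and the 5 strongest shared regions away from gene ends. SETD1B was named after its values were seen. Folds are given as replicate 1 and replicate 2, each being the highest among the regions at that gene's ends, which need not be the same region in both.

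Alternatives fixed beforehand were a −log10 q of at least 5, the strongest 20000 regions of each list by −log10 p, an overlap of at least 50% of both regions, windows of 500 and 2500 bp, neighbourhoods of 100 kb and each replicate alone. Neighbourhood counts of all lists were repeated with the strongest 20000 regions and without the class of 219 to 225 bp, and those of luminal genes also under the other settings. The class of 219 to 225 bp is the longest run of widths below 300 bp whose median fold was above that of all regions in both replicates, a rule written after the widths were seen. Leaving out that class, lists matched on gene density and the moved lists were added after the data were seen. Analyses ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. On simulated data the overlap routine returned the shares it was given. With lists of 25 genes among 19970, Fisher's test called 6% of 200 unchanged lists and 88.5% of lists made accessible at a rate of 90%. The matched-list test called 0 of 40 unchanged lists and 72.5% of lists with counts raised 2-fold. These simulated lists held scattered genes with independent values and were judged without adjustment. They do not cover lists of neighbours that share regions.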

Results

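Chromatin accessibility was profiled by ATAC-seq in MCF-7, an oestrogen receptor-positive luminal breast cancer cell line. In this assay the Tn5 transposase inserts sequencing adapters into open DNA, so that fragments pile up at nucleosome-depleted promoters and enhancers. The data are 1 group of 2 wild-type, untreated libraries, and nothing in the labels says whether they came from separate cultures. The wider study concerns the zinc finger protein ZNF408, the H3K4 methyltransferase SETD1A and immune escape in breast cancer; its knockdown and CUT&Tag libraries were not analysed here. The comparisons that the design allows are therefore between the 2 replicates, between accessible regions and the rest of the genome, and between gene groups within this cell line. Each replicate is a list of peak calls. Replicate 1 held 135166 rows over 113510 regions and replicate 2 held 138937 rows over 118249 regions. On chromosomes 1 to 22 and X there were 113255 regions (45.9 Mb, median width 307 bp) in replicate 1 and 117997 regions (46.6 Mb, median width 303 bp) in replicate 2. The lists carry no read counts, so the sequencing depth behind each region is unknown.

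The first question was how far the 2 libraries gave the same accessible sites. Of the replicate 1 regions, 96503 overlapped a replicate 2 region by at least 1 bp, which was 85.2% (95% Wilson interval 85.0 to 85.4). Of the replicate 2 regions, 97420 overlapped replicate 1, which was 82.6% (82.3 to 82.8). The mean of both directions was 83.9% ± 1.87 (SD of the 2 directions). Both directions come from the same pair of lists, so this SD does not measure variation between replicates. Randomly placed regions of the same widths overlapped in 3.18% ± 0.0623 and 3.04% ± 0.0484 of cases (SD over 10 placements). The overlapping calls joined into 95364 shared regions, and the base-pair Jaccard index was 0.647. Overlap depended on the strength of a region within its own list. In the weakest decile of replicate 1, 44.4% of regions were found in replicate 2, and in the weakest decile of replicate 2, 39.9% were found in replicate 1. In the strongest decile of either list 100% were found in the other. The intervals cover counting error over regions and not the spread between cultures.

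**Figure D1:**
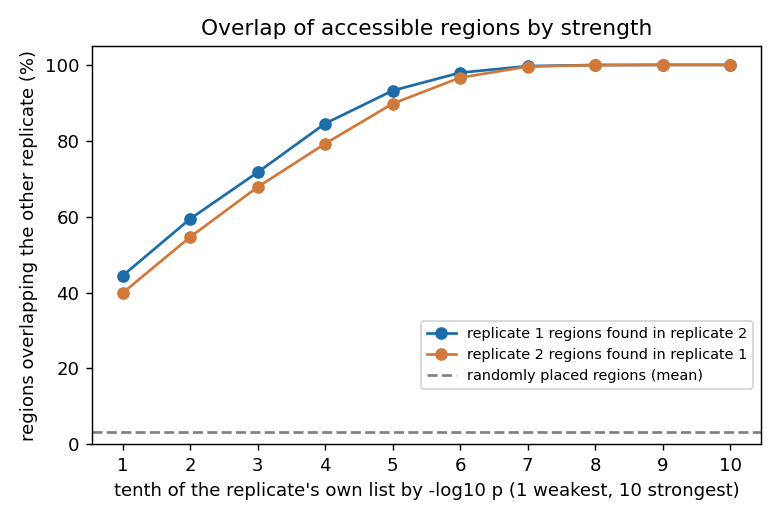
Share of regions that overlap the other replicate (y axis, percent) against the decile of the replicate's own list ranked by the peak caller's -log10 p (x axis, 1 weakest, 10 strongest), with 1 line per replicate and the mean of randomly placed regions as a dashed line. Overlap rose from 44.4% and 39.9% in the weakest deciles to 100% in the strongest, against about 3% for random placement.

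Both lists held a class of narrow, strongly enriched regions of 219 to 225 bp. It made up 16892 regions (14.9%) in replicate 1 and 17292 regions (14.7%) in replicate 2. A width of 219 bp alone occurred 6357 times in replicate 1 and 6478 times in replicate 2, whereas a width of 218 bp occurred 252 and 265 times. The class was defined after its widths were seen, as the longest run of widths below 300 bp whose median fold lay above that of all regions in both replicates, so its higher fold follows from the definition. The median fold enrichment given by the authors' peak caller was 13.5 in this class and 6.18 in all other regions of replicate 1, and 12.99 against 6.19 in replicate 2. Among regions with a fold above 20, the class made up 5537 of 6110 (90.6%) in replicate 1 and 5515 of 6116 (90.2%) in replicate 2. Of 13425 shared regions of this class, 94.2% had the same first and last base in both replicates, against 2.07% of the 81939 other shared regions. Without the class, 81.0% of replicate 1 regions and 78.3% of replicate 2 regions overlapped the other list.

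**Figure D2:**
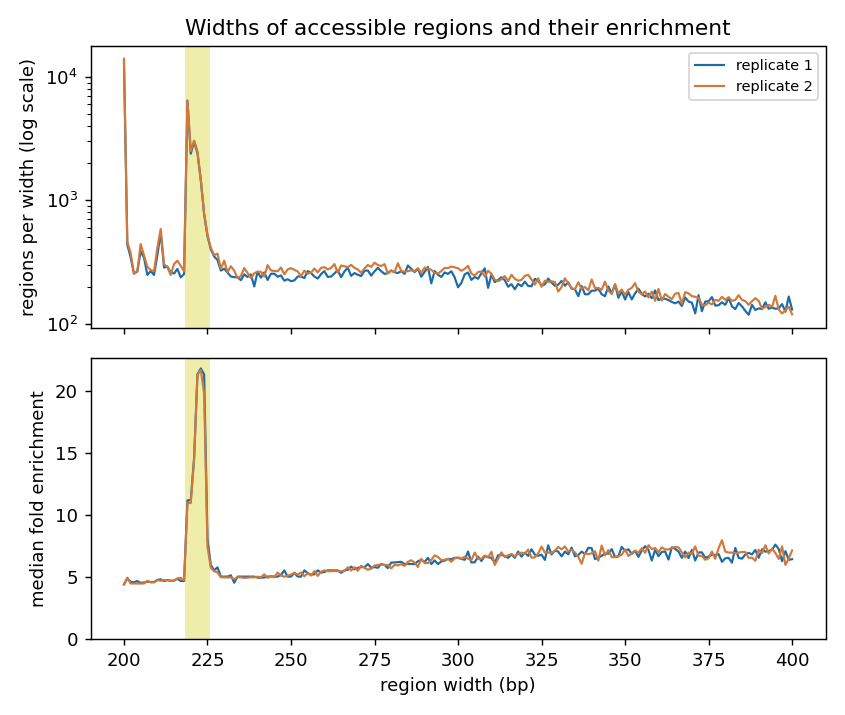
Number of regions of each width (upper panel, log scale) and their median fold enrichment (lower panel) against region width in bp, with 1 line per replicate and the widths from 219 to 225 bp shaded. Both replicates show the same spike at 219 bp, with 6357 and 6478 regions, and a higher median fold within the shaded widths than on either side.

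The next question was where accessible chromatin lay relative to genes. Of the 95364 shared regions, 13687 (14.4%, 95% Wilson interval 14.1 to 14.6) lay within 1000 bp of an annotated end of a protein-coding gene, a window that covers 2.39% of the genome. Randomly placed regions of the same widths fell there in 3.12% of cases. A further 42.8% lay elsewhere in gene bodies and 42.8% lay outside genes, against 40.7% and 56.2% for random placement. The share near gene ends differed by width. It was 8.30% (7.89 to 8.73) for shared regions of 300 to 400 bp and 32.1% (31.6 to 32.7) for those over 600 bp. In the narrow class of 219 to 225 bp it was 1.57% (1.37 to 1.80), below the 2.54% of randomly placed regions of those widths. Because the gene table used here gives no strand, the promoter end of a gene was not told from its 3' end.

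By the planned rule, the 5 strongest shared regions away from gene ends all belonged to the narrow class. The first lay on chromosome 7 from 136294654 to 136294875 (GRCh38), 317294 bp from MTPN, with a fold of 48.2 in both replicates. The second lay in the body of RAP1GDS1 (chromosome 4, 98389994 to 98390214), with folds of 47.2 and 47.0. The other three lay in the body of ZPBP (chromosome 7, 49935999 to 49936220, folds 46.9 and 46.7), 134367 bp from BANK1 (chromosome 4, 101656142 to 101656362, folds 46.5 and 46.7) and 144698 bp from SARAF (chromosome 8, 29918083 to 29918304, folds 46.5 and 46.3). Leaving out the class did not remove all strong regions, although those given next had lower folds. Among shared regions wider than 230 bp, a set chosen after the data were seen, the 5 strongest away from gene ends had widths of 231 to 313 bp and folds from 39.3 to 45.3. The nearest genes to these were KCNJ18, KIF5C, KCNU1, GYPC and SMARCA2.

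Gene ends were accessible, meaning that a peak of each replicate lay within 1000 bp of either end, in 12428 of 19970 protein-coding genes (62.2%, 95% Wilson interval 61.6 to 62.9). The share was 65.7% in replicate 1 alone and 64.5% in replicate 2 alone. At 1680 genes both ends were accessible in both replicates, at 10735 genes 1 end was, and at 13 genes the replicates had peaks at different ends. The gene the study is named for, ZNF408 (chromosome 11, 46701031 to 46705912), had a region over its lower-coordinate end in both libraries, with folds of 11.1 and 11.03 (46700230 to 46701514 in replicate 1). SETD1A (chromosome 16, 30957754 to 30984664) had folds of 8.77 and 10.6 in a region outside the gene, beyond its upper-coordinate end (30984862 to 30985328 in replicate 1). Regions counted at a gene end can lie outside the gene and, as no strand was used, at its 3' end. They may also belong to a neighbouring gene. The folds given for SETD1A are the highest over both ends and do not describe its lower-coordinate end. 18 gene lists, fixed before the data were examined, were compared with all other protein-coding genes by Fisher's exact test (two-sided, Benjamini-Hochberg over the 18 lists). 5 lists had more accessible ends than other genes, 6 had fewer and 7 did not pass the test. Genes of 1 cell line, not samples, are the unit, and neighbours can share a region; when each list was moved as 1 block along the gene order, the calls of 5 lists with more and 5 with fewer accessible ends held. In the strongest 20000 regions of each replicate, 15.3% of genes were accessible. There the calls of MHC class I, olfactory receptor and 20q13 and 17q23 genes held and the other 8 ended. In the strongest decile the narrow class made up 49.6% of regions in replicate 1 and 46.7% in replicate 2.

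Genes of MHC class I antigen presentation, which load and display peptides for T cells, were accessible at 22 of 22 members (adjusted p = 3.57e-04, Fisher's exact test). HLA-A, a classical class I heavy chain gene, had folds of 16.2 and 17.8. HLA-F, a non-classical one, had 16.7 and 15.8. TAP2, a subunit of the peptide transporter, had 13.9 and 13.5, and B2M, the light chain gene, had 11.7 and 11.7. Interferon response genes were accessible at 32 of 36 members (88.9%, adjusted p = 1.90e-03, Fisher's exact test). IFI6 (14.5 and 13.5), the transcription factor gene STAT2 (13.3 and 13.8) and STING1 (12.8 and 12.6), which encodes the adaptor of cytosolic DNA sensing, had the strongest ends of this list. IFI27, TRIM22 and XAF1 had no peak at their ends in either replicate. HLA genes have near-identical relatives, and how reads shared between them were placed is not given in the sources used here.

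MHC class II, checkpoint ligand and chemokine and cytokine genes did not pass the test. The class II list, which holds regulators such as RFX5 as well as class II molecules, was accessible at 10 of 17 members (58.8%, adjusted p = 0.805, Fisher's exact test). HLA-DMB had folds of 16.6 and 16.3, and RFX5, a regulator of class II promoters, had 15.2 and 16.5. The peak beside HLA-DRA (21.9 and 23.2), outside the gene, belonged to the narrow class. CD74, HLA-DOB and HLA-DPA1 had no peak at their ends, though CD74 and HLA-DPA1 each held 2 shared regions within the gene. Immune checkpoint ligand genes were accessible at 22 of 29 members (75.9%, adjusted p = 0.201, Fisher's exact test). The ends of CD274, which encodes PD-L1, had folds of 5.84 and 4.57, while ENTPD1 had 18.5 and 16.6. A region beside CD70, outside the gene, had 14.0 and 13.9, and ULBP2, an NKG2D ligand gene, had 11.1 and 12.9. CD86, ICOSLG and IDO1 had no peak at their ends. Chemokine and cytokine genes were accessible at 17 of 36 members (47.2%, adjusted p = 0.101, Fisher's exact test). A region beside IL10 (20.1 and 20.1), the neutrophil chemokine gene CXCL8 (11.5 and 11.8) and IL18 (12.3 and 11.3) led this list, and CCL17, CCL19 and CCL2 had no peak at their ends.

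Luminal and oestrogen receptor genes were accessible at 24 of 30 members (80.0%, 62.7 to 90.5), which missed the threshold (adjusted p = 0.0795, Fisher's exact test). It passed when the narrow class was left out, with the same 24 of 30 (adjusted p = 0.0495, Fisher's exact test), and in either replicate alone, with 26 of 30 in each (adjusted p = 0.0312 and 0.0176, Fisher's exact test). Over all alternatives its adjusted p ran from 0.0159 to 0.734 (Fisher's exact or permutation tests). The luminal regulators GATA3 (5.85 and 4.92) and FOXA1 (5.35 and 7.46, beside the gene) and the oestrogen-induced genes TFF1 (9.68 and 10.9) and GREB1 (5.51 and 7.08) were accessible in both replicates. The receptor tyrosine kinase gene ERBB3 had folds of 15.0 and 12.8 in a region outside the gene. This region lay beyond the upper-coordinate end (56103967 to 56105068 in replicate 1) and may belong to a neighbouring gene. These folds do not describe the other end of ERBB3. KRT8 and KRT18, the luminal keratin genes, are neighbours and shared 1 region, with folds of 10.9 and 10.5. PGR, the progesterone receptor gene, had a peak at its ends in replicate 2 only (5.86). ESR1, the oestrogen receptor gene, had no peak at either outer end of its annotated span (chromosome 6, 151656672 to 152129619) but held 13 shared regions within it; internal promoters were not tested. KRT19 had none at its ends.

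Genes of the basal and myoepithelial lineage, the other epithelial layer of the breast, were accessible at 8 of 20 members (40%, adjusted p = 0.0795, Fisher's exact test). Without the narrow class the count was 7 of 20 and the difference passed (adjusted p = 0.0312, Fisher's exact test), since the peak at TP63 (13.6 and 9.50) belonged to it; over all alternatives the adjusted p ran from 0.0312 to 0.551 (Fisher's exact or permutation tests). OXTR (15.9 and 12.9) and LAMC2 (9.59 and 10.4) were accessible, while CNN1, DSG3 and KRT14 had no peak at their ends. CNN1 and DSG3 each held 1 shared region within the gene. Mesenchymal and fibroblast genes were accessible at 11 of 22 members (50%, adjusted p = 0.289, Fisher's exact test). PDGFRB (10.9 and 10.3), PDGFRA (9.69 and 10.4) and ZEB1 (6.85 and 8.01) had peaks, those of PDGFRB and PDGFRA lying outside the gene. COL3A1, COL6A3 and DCN had none at their ends but held 2, 1 and 1 shared regions within the gene.

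Of the lists for lymphocytes, myeloid cells, endothelium, hepatocytes and neurons, all but the myeloid one passed the test with fewer accessible ends than other genes; the mesenchymal list, given above, did not pass. T, NK and B lymphocyte genes were accessible at 6 of 25 members (24.0%, adjusted p = 5.44e-04, Fisher's exact test). Among the strongest 20000 regions, 4 of 25 members (16%) were accessible against 15.3% of all genes, and the call ended (adjusted p = 0.833, Fisher's exact test). The direction turned there by a margin that a single gene could reverse. Over all alternatives the adjusted p ran from 3.41e-05 to 0.833 (Fisher's exact or permutation tests). The strongest peak in this list, beside CD2 (40.8 and 39.98) and outside the gene, belonged to the narrow class and was lost without it. CD3E (19.5 and 18.4, outside the gene) and CD247 (16.0 and 16.3) had wider regions, and CD19, CD3G and CD5 had no peak at their ends. Endothelial genes were accessible at 4 of 18 (22.2%, adjusted p = 1.90e-03, Fisher's exact test), with ESAM (12.8 in replicate 1 and 7.04 in replicate 2, at opposite ends of the gene), KDR (8.06 and 5.98) and ROBO4 (4.55 and 4.14) among the 4, and no peak at the ends of CDH5, CLDN5 or EGFL7. At 2500 bp either side, 9 of 18 were and the call ended (adjusted p = 0.0927, Fisher's exact test; 7.34e-04 to 0.246 over all alternatives). Hepatocyte genes were accessible at 4 of 20 (20%, adjusted p = 7.87e-04, Fisher's exact test). TAT had folds of 8.15 and 13.4, in a region mostly outside the gene at its lower-coordinate end. APOA1 had 8.82 and 7.73, and TF, the transferrin gene, had 5.33 and 7.07. AHSG, ALB and APOA2 had no peak at their ends. Neuronal genes were accessible at 7 of 20 (35.0%, adjusted p = 0.0306, Fisher's exact test), and at 12 of 20 with 2500 bp either side, where the call ended (adjusted p = 0.440, Fisher's exact test; 2.42e-03 to 0.833 over all alternatives). SYT1 (12.1 and 11.9), TUBB3 (7.55 and 6.99) and SNAP25 (5.49 and 7.07) had peaks, those of SYT1 and SNAP25 at the upper-coordinate end. ELAVL4, GABRA1 and GAD1 had none at their ends but held 2, 1 and 4 shared regions within the gene. Myeloid genes missed the threshold at 9 of 22 (40.9%, adjusted p = 0.0712, Fisher's exact test) and passed it without the narrow class at 8 of 22 (adjusted p = 0.0362, Fisher's exact test) and in replicate 2 alone at 9 of 22 (adjusted p = 0.0355, Fisher's exact test; 0.0179 to 1 over all alternatives). FCGR3A (12.5 and 12.6, outside the gene) and CD14 (10.2 and 12.9) had peaks, and CSF1R shared its region with the adjacent PDGFRB. AIF1, CD163 and CD33 had none at their ends, though CD163 held 2 shared regions within the gene.

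Olfactory receptor genes, a family usually silent outside sensory neurons, set the low end of the range. 26 of 392 were accessible (6.63%, adjusted p = 2.23e-121, Fisher's exact test), and 19 of 392 without the narrow class. The peaks beside OR1N1 (32.7 and 30.6) and OR5D13 (21 and 20.8), outside the genes, belonged to that class. The peak beside OR5T2 (36.1 and 35.2), also outside the gene, was 230 bp wide, just above the widths of the class. Its boundaries were the same in both replicates, and OR5T2 stayed among the 19. OR10A2, OR10A3 and OR10A4 had no peak at their ends. Ribosomal protein genes, active in every cell, were accessible at 81 of 84 members (96.4%, adjusted p = 1.15e-12, Fisher's exact test). RPL15 (16.0 and 16.5), RPS5 (13.9 and 13.1) and RPSA (12.3 and 12.3) led this list. The peak of RPL15 was of the narrow class, outside the gene, and the gene had another region at its ends. RPL10L and RPL26L1 had no peak at their ends. Genes of the H3K4 methyltransferase complexes, to which SETD1A belongs, were accessible at 21 of 22 members (95.5%, adjusted p = 1.82e-03, Fisher's exact test). MEN1 (16.5 and 16.0), BOD1 (12.1 and 11.8) and RBBP5 (10.4 and 12.3) were the strongest, and SETD1B had a peak at its ends in replicate 2 only.

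**Figure D3:**
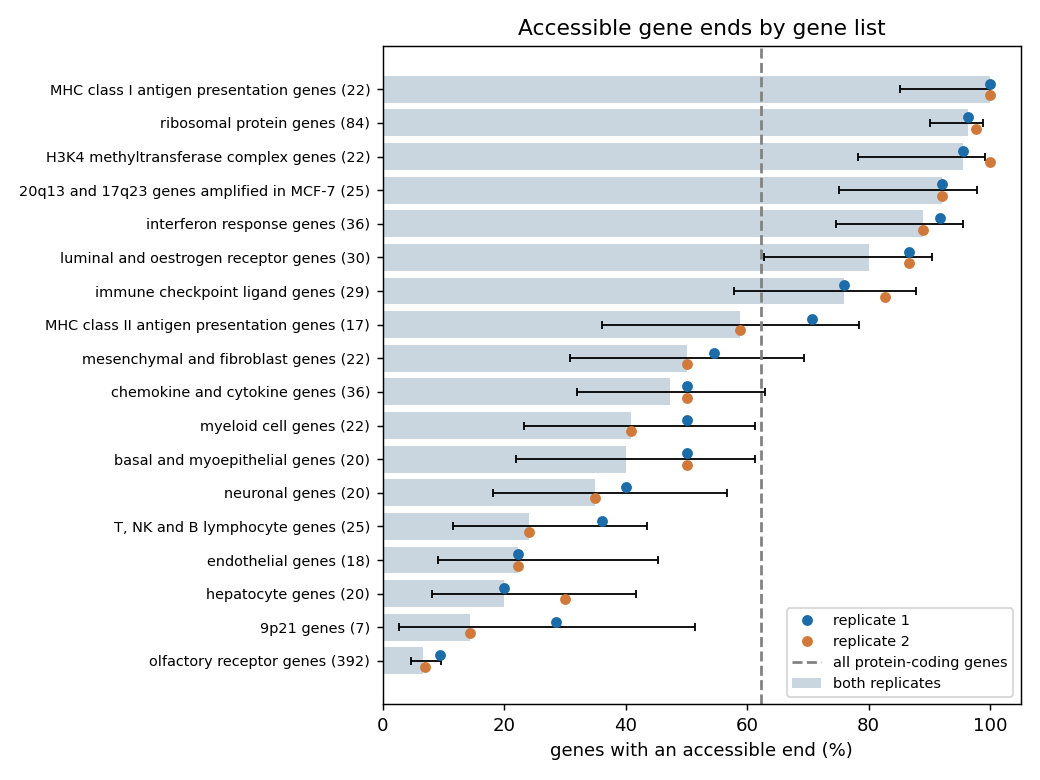
Percentage of genes in each list (number of genes in brackets) with a peak within 1000 bp of either end. Bars are genes accessible in both replicates with 95% Wilson intervals, points are each replicate alone, and the dashed line is the 62.2% of all protein-coding genes; shares run from 6.63% of olfactory receptor genes to 100% of MHC class I genes.

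Copy number in MCF-7 is far from diploid, and 2 lists covered loci with known changes. Genes of 20q13 and 17q23, which are amplified in MCF-7, were accessible at 23 of 25 members (92.0%, adjusted p = 2.86e-03, Fisher's exact test). BCAS3 (16.1 and 15.1), the helicase gene BRIP1 (14.4 and 15.0) and MED13 (13.6 and 14.1, outside the gene) had the strongest ends. PREX1 and USP32 had no peak at their ends. These genes had a median of 7 shared regions within 50 kb of an end, against 4 in random lists matched on gene density (middle 95% of lists 3 to 5.5; adjusted permutation p = 0.0072). Luminal genes had a median of 5.75 regions against 4.5 in matched lists (3.25 to 5.75; adjusted permutation p = 0.14). MHC class I genes had 7.75 against 5.75 (adjusted permutation p = 0.108) and checkpoint ligand genes 6.5 against 4.5 (adjusted permutation p = 0.0648). Of 18 lists, olfactory receptor genes (1 against 6; adjusted permutation p = 0.0036) and 9p21 genes (0.5 against 4.5; adjusted permutation p = 0.0072) were the other two that passed. Among the strongest 20000 regions of each replicate, 9p21 genes no longer passed (0 against 0.5; adjusted permutation p = 1) and MHC class I genes did (2 against 1; adjusted permutation p = 0.0228). Without the narrow class, ribosomal protein genes also passed (7 against 5.5; adjusted permutation p = 0.0279). Members of the 9p21, 20q13 and 17q23 lists are neighbours that share regions. When each list was moved as 1 block along the gene order, the neighbourhood counts no longer passed for 20q13 and 17q23 (adjusted permutation p = 0.163) or for 9p21 (adjusted permutation p = 0.251).

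MCF-7 is known to have lost CDKN2A, which encodes the tumour suppressors p16 and ARF, by homozygous deletion. CDKN2A (chromosome 9, 21967752 to 21995324) and CDKN2B had no peak at either end in either replicate. The interval without any peak ran from 21954510 to 22051186, a length of 96.7 kb, longer than that of 90.8% of protein-coding genes; the median over these genes was 25.4 kb. It was 267 kb when only peaks with a −log10 q of at least 5 were kept. Of 7 genes at 9p21, 1 was accessible (14.3%, adjusted p = 0.0247, Fisher's exact test), and this call did not hold when the list was moved as 1 block (adjusted permutation p = 0.191) or in replicate 1 alone, where 2 of 7 were accessible (28.6%, adjusted p = 0.0742, Fisher's exact test; 5.56e-03 to 0.734 over all alternatives). The accessible gene was MTAP, through a 200 bp region with folds of 4.55 and 3.998. It ran from 21941496 to 21941695 in replicate 1 and from 21941474 to 21941673 in replicate 2. Replicate 2 also had a 546 bp region at the other end of MTAP (21802226 to 21802771, fold 3.998). Regions of 200 bp, the smallest width, had median folds of 4.42 and 4.41 in the 2 lists. With a −log10 q of at least 5, 0 of 7 genes at 9p21 were accessible. Like CDKN2A and CDKN2B, DMRTA1 had no peak at its ends. With the narrow class left out and peaks of either replicate still counted, the interval was 109 kb. Counting only shared regions outside the class, a looser rule, it was 215 kb, from 21941696 to 22157107. That interval held 3 shared regions of the narrow class, with a median fold of 26.2 in replicate 1 and 27.3 in replicate 2. Their density was 13.9 per Mb against 4.43 per Mb over the genome, a value that rests on these 3 regions.

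**Figure D4:**
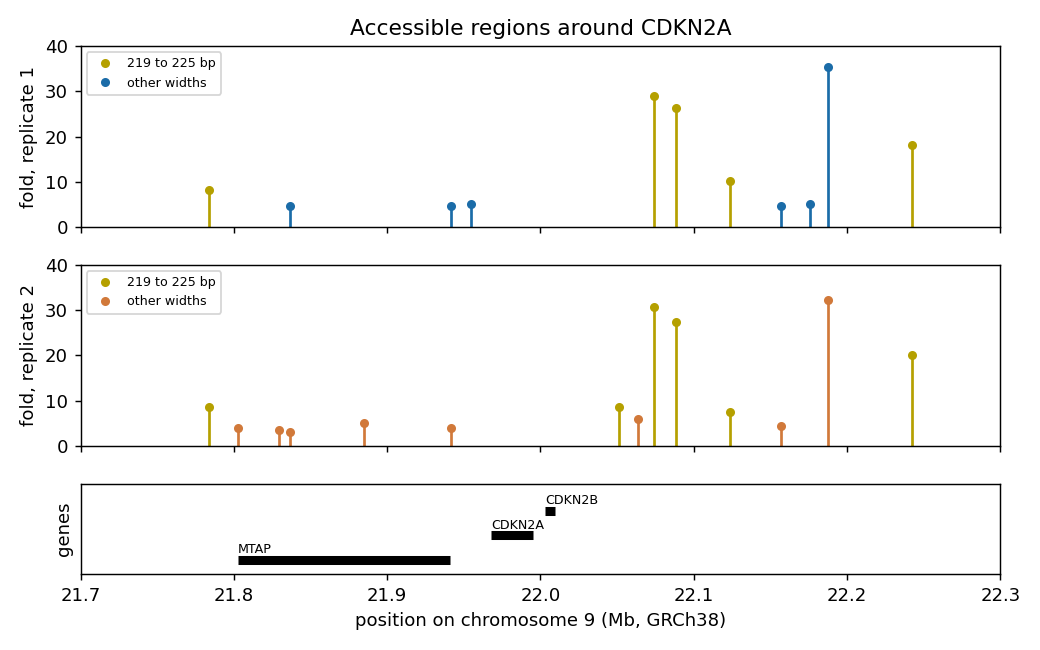
Fold enrichment of each accessible region (y axis) by its position on chromosome 9 in Mb on GRCh38 (x axis), 1 panel per replicate, with protein-coding genes below. No region lies over CDKN2A or CDKN2B, and several of the strongest regions to their right have widths of 219 to 225 bp.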

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

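Regions on sequences that are not placed on a chromosome were outside the comparisons. There were 171 such regions on 48 sequences in replicate 1 and 164 on 50 sequences in replicate 2, and 123 were shared. They are given because signal lay there at all (a count of 0 would allow 3); whether their number is unusual was not tested. 1 sequence held 20 of the shared regions and another held 16. The highest fold among them was 39.1 in replicate 1 and 38.9 in replicate 2.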

How the results depend on the processing

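Leaving out the regions of 219 to 225 bp and matching on gene density were chosen after the data were seen. The planned motif searches, CpG matching, transcript starts and repeat or mitochondrial filters were not run, since no genome sequence was used. No paired analysis was possible because there is 1 group. The share of regions found in the other replicate, 83.9%, became 86.4% at a −log10 q of at least 5, 76.7% with an overlap of at least 50% of each region and 79.7% without the narrow class. The share of shared regions near gene ends, 14.4%, became 15.2% at the q limit, 15.0% in the strongest 20000 regions, 13.5% with 50% overlap, 11.8% at 500 bp, 18.7% at 2500 bp and 17.2% without the narrow class, and 13.5% to 13.8% in single replicates. The share of genes with an accessible end, 62.2%, became 56.9% at the q limit, 15.3% in the strongest 20000 regions, 56.4% with 50% overlap, 55.7% at 500 bp, 71.8% at 2500 bp and 61.2% without the narrow class, and 64.5% to 65.7% in single replicates. The strongest 20000 regions leave few genes accessible, and calls ended there for endothelial (0%), hepatocyte (0%), neuronal (10%), interferon response (22.2%), H3K4 methyltransferase (22.7%), 9p21 (0%) and ribosomal protein genes (22.6%). Lymphocyte genes turned from fewer to 16% there, against 15.3% of all genes (adjusted p = 0.833, Fisher's exact test; 3.41e-05 to 0.833 over the alternatives). At 2500 bp the calls for endothelial (50%) and neuronal genes (60%) ended and luminal genes passed (93.3%). The 9p21 call (14.3%) ended at 500 bp and with 50% overlap, at 14.3% in both, and without replicate 2; its single-replicate shares were 14.3% and 28.6%. Myeloid genes passed at 500 bp (27.3%) and without replicate 1; their single-replicate shares were 40.9% and 50%. Luminal genes passed in each single replicate, at 86.7% in both. Without the narrow class, luminal (80.0%), basal (35.0%) and myeloid genes (36.4%) passed. Matching on gene density kept the call and direction of all 18 lists, and a q limit did so too. Neighbourhood counts of luminal genes, a median of 5.75, were 7.5 to 8.25 in single replicates and then passed (adjusted permutation p = 0.0187 and 0.006). The interval without peaks at CDKN2A, 96.7 kb, was 267 kb at the q limit, 1220 kb in the strongest 20000 regions, 109 kb without the narrow class and 109.5 to 119 kb in single replicates. The causes were not tested, apart from the fewer regions that a stricter limit leaves. Unknown depth limits any reading of a missing peak.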

Other observations

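The tests of even placement along the genome, of shared neighbours and of the separate lymphocyte and myeloid lists, and the counts by kind of gene and by bin, were chosen after the data were seen. The condition on the adjusted p in the test of shared neighbours was added once its value was known, and BCAS4, CEBPB, PTPN1, RELA and FOSL1 were named after their values were seen.

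Genes that do not encode proteins differed widely in accessibility. Of 18177 lncRNA genes, 31.9% had a peak of both replicates within 1000 bp of an end, and 22.9% of the 14099 whose windows did not touch those of a protein-coding gene. For 443 tRNA genes the share was 61.6%, close to that of protein-coding genes, and 55.2% of the 368 away from protein-coding ends. It was 32.5% of 154 snRNA genes, 18.6% of 1911 miRNA genes, 10.7% of 1196 snoRNA genes and 8.05% of 15212 pseudogenes not annotated as transcribed, against 30.3% of 1246 transcribed pseudogenes. tRNA and snRNA genes have near-identical copies, so the placement of their reads is uncertain. In short genes such as these the windows at both ends overlap, so less sequence was searched per gene than in most protein-coding genes. The shares were not corrected for this.

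Accessible regions were unevenly spread along the genome. Leaving out the narrow class of 219 to 225 bp, shared regions were densest on chromosome 19 (48.4 per Mb), chromosome 17 (43.9 per Mb) and chromosome 20 (38.5 per Mb), and sparsest on chromosome X (13.8 per Mb) and chromosome 13 (17.2 per Mb). Per protein-coding gene the order differed, with 1.95 regions on chromosome 19, 2.54 on X, 4.61 on chromosome 20 and 6.13 on chromosome 18. In bins of 1 Mb, whose median was 24 regions over 3043 bins, the highest count was 111, on chromosome 20 from 50000001 to 51000000. That bin holds 12 protein-coding genes, among them BCAS4, known for its fusion with BCAS3 in MCF-7, the transcription factor gene CEBPB and the phosphatase gene PTPN1. The next bin, with 106 regions and 49 genes, lay on chromosome 11 from 65000001 to 66000000 and holds RELA and FOSL1.

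The narrow regions of 219 to 225 bp, a class chosen for its fold, made up 90.6% and 90.2% of regions with a fold above 20, and 94.2% of those shared had the same boundaries in both replicates. Their place differed from that of wider regions: 1.57% lay within 1000 bp of a gene end, against 8.30% of shared regions of 300 to 400 bp. Of randomly placed ones 2.54% did, and the bound written beforehand, within 1.5 times the random share, was met only on its upper side. The share was 4.35% for shared regions narrower than 219 bp and 7.24% for those of 226 to 300 bp. This cannot decide on regulatory DNA, since enhancers away from gene ends are not covered. Narrow sites near gene ends could also have merged into wider regions, which would lower the share. Positions spread evenly along the genome are argued against. Of regions over 200 bp from any region of another width, with which they could have merged, 1.55% (1.35 to 1.77) lay near gene ends. The share was 2.04% (1.96 to 2.11) of random ones, a difference of -0.490 percentage points. The caller's merging distance is not given in the sources used here, and the intervals were apart at the distances tried from 0 to 1000 bp but not at 2000 bp. The number per chromosome followed chromosome length (r = 0.959 across 23 chromosomes) more closely than the number of other shared regions (r = 0.776; bootstrap interval of the difference 0.0626 to 0.360), yet it ranged from 2.00 per Mb on chromosome 19 to 5.69 per Mb on chromosome 4. Positions fixed by the sequence itself stay open, a candidate source being short reads that match the Tn5 recognition end, whose length is the 19 bp between 219 bp and the smallest width; this needs the genome sequence, and the single group allowed no comparison between conditions.

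Genes of 20q13 and 17q23 had 1.75 times as many shared regions nearby as random lists. Against lists matched on gene density the median lay at percentile 99.97. Those lists were drawn gene by gene and do not keep neighbours together, so gene density is argued against only for genes that do not share regions. More copies raising weak calls cannot be told apart: the ratio over all regions was 0.4375 of the ratio of 4 among the strongest 20000, but that ratio is a median of 2 over 0.5, and the -log10 p that ranks regions can itself rise with copy number, so the bound written beforehand was a poor one. Neighbouring genes that count the same regions cannot be told apart from a real excess: among lists moved as 1 block the median lay at percentile 98.13, with a permutation p of 0.0376 that became 0.163 on adjustment over the lists; without that adjustment shared neighbours would have been argued against. Extra copies that raise strong and weak calls alike also stay open.

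Lymphocyte genes had fewer accessible ends than other genes, while the myeloid list missed the threshold. For lymphocyte genes sparse gene neighbourhoods are argued against, since their share was 38.5 percentage points below the mean of density-matched lists (a difference of -38.5) and below the 44.0% that bounds the middle 95% of them. For myeloid genes the difference was -22.0 percentage points and the share lay on their lower bound, 40.9%, so sparse neighbourhoods cannot be told apart there. CpG content of the promoters, which was not measured here, stays open for both, and no biological explanation was tested in a single group.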
